A study of Capra hircus with 6 samples.

How the data were processed

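Pineal glands of female goats (Capra hircus) from 2 stages, prepuberty and puberty, were measured by RNA sequencing, with 3 libraries per stage. Total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. That kit does not mark the strand, and the strand setting of the counting is not given in the sources used here. The submitters' processing notes list CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, without the role or settings of each. The same notes list the human builds GRCh38 and hg38, whereas the gene identifiers of both tables are goat Ensembl identifiers. The tables name no build, so coordinates are given as the authors' tables list them. Of 13272 symbols found once in these tables and in a goat gene table of assembly ARS1.2, 96.5% lay on the same chromosome at overlapping positions. No reference genome was used here, so GC content was not examined.

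The deposited count table holds the authors' raw read counts per gene, as whole numbers without normalization, for 28244 genes, of which 5944 had 0 counts in all 6 libraries. The deposited FPKM table holds, for the same genes, the authors' FPKM values. Each FPKM value equalled the count divided by the listed gene length and by 1 constant per library, with a largest relative deviation of 5.11e-15. These constants matched each library's DESeq2 size factor multiplied by the geometric mean of the library totals. FPKM values were used only for an alternative test. Of the protein-coding genes, 65.2% had a listed length divisible by 3, so many gene models hold a coding sequence without untranslated regions. Genes with an identifier but no symbol held 21.7% of all counts, stayed in the library totals and in the tests, and are not named. AANAT, the penultimate enzyme of melatonin synthesis, matched no symbol in the tables and was not analysed here.

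Library totals ran from 18864451 to 20971065 counts. Genes were kept by edgeR's filterByExpr with its minimum count of 10, which left 16588 genes for testing, 4322 of them without a symbol, and set 11656 aside. The tested genes held at least 99.9% of the counts of each library. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood fit with robust estimation and quasi-likelihood F test, in R 4.3.3) for puberty against prepuberty, with no covariate. Fold changes are puberty over prepuberty, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.18. CPM values use the TMM-scaled totals, and log2 CPM values used a prior count of 2. A standard error of a log2 fold change was taken from the fold change and its F statistic, and intervals cover 95%. All p-values of single genes named in the text are adjusted p-values from this test unless another test is named. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical.

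Gene lists were fixed before the data were examined. They comprise 37 lists with 1046 different genes, of which 795 had a symbol in the tables, 3 of them only in another letter case, and 688 were tested. The lists cover melatonin synthesis, the pinealocyte, signalling, hormones, the clock, DNA methylation, metabolism, stress, RNA quality and markers of other cell types that the tissue could hold. Camera (limma 3.58.1) compared each list of at least 5 measured genes with all other genes at a preset correlation of 0.01, which left 35 lists, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list and fry were run as alternatives. Members called singly were counted over all genes tested and again adjusted over the list alone.

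The genes named were chosen by a rule set before the data were examined. The first part took called genes with a symbol, a mean of at least 1 CPM over the 6 libraries and no overlap between the groups, and from them the 12 largest rises and the 12 largest falls by log2 fold change. The second part took TPH1, DDC, AANAT and ASMT. The third took the 4 members with the smallest p in the direction of each list that passed camera. The last took up to 4 called members of every list, by smallest p. Together these parts named 91 genes, a few of which are not reported here. TTR, the choroid plexus markers beside it and the protein domain families were chosen after their values were seen.

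The alternatives set before the data were examined were RLE scaling, no count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a block for the replicate number, an adjusted p under 0.1, a minimum absolute log2 fold change of 1, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), both other list tests, and leaving out each library. Fold changes of the FPKM tests are on the log2(FPKM + pseudocount) scale, which understates the change of low genes. Offsets that depend on gene length, from a loess curve of span 0.3 per library or from medians in 20 length bins, and thinning of all libraries to the smallest total were added after seeing the data. The closing section gives their effects.

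The tests were first run on simulated counts for the 16588 genes, drawn from the means, totals and dispersions of these libraries, with 200 changed genes. The edgeR test called 27% of the 100 genes changed 1.5-fold and 67% of the 100 genes changed 2-fold in the right direction, and of its 109 calls 15 were unchanged genes. On the same counts DESeq2 called 37 unchanged genes and limma-voom 11. Camera gave the list that had been shifted an adjusted p of 3.4e-12 and called 1 of 30 unshifted lists. The simulated genes were drawn independently and put in lists at random. These values therefore do not hold for lists whose genes move together. A simulated length trend without changed genes gave 1 call with and without length-dependent offsets, and the offsets moved Spearman's rho of log2 fold change and length from -0.47 to 0.00013. With no changed gene, the adjustment leaves few calls in either fit. These 2 counts therefore do not show how many calls such a trend adds where many genes change.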

Results

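The libraries were made to follow the transcriptome of the pineal gland, the melatonin-secreting gland of the brain, through the onset of puberty in female goats. Puberty had been judged by inflammation of the vulva and by mature follicles in ovarian sections, per the series description. DNA methylation, which the study also measured, was not analysed here. The prepuberty libraries held 18864451, 20247370 and 19005344 counts and the puberty libraries 20971065, 18963195 and 20322677. Spearman's correlation of the libraries across genes was 0.982 to 0.989 within groups and 0.972 to 0.982 between groups. Genes are not independent replicates, and these values are descriptive. Counts of libraries of 1 group differed by 17.1 to 38.5 times the chi-square that sampling alone gives, so no library was a second copy of another. The first principal component of log2 CPM held 36.8% of the variance and placed the 3 prepuberty libraries on 1 side and the 3 puberty libraries on the other. The second held 20.9%, and puberty replicate 2 lay farthest out on both.

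The comparison of puberty with prepuberty asked which genes changed in the pineal gland across this transition. The axon guidance receptor DCC and 3 genes of the cell cycle list were among the largest falls. DAO, which encodes D-amino acid oxidase, the dynein gene DYNC1I1 and the homeobox gene SHOX2 were among the largest rises. Transcripts of the respiratory chain and of the cytosolic ribosome were higher in puberty, with list medians of 0.41 and 0.44 on the log2 scale, and genes that carry out cell division were lower, with a median of -0.41. These list calls were made at a preset correlation and were lost with an estimated one (adjusted p = 0.25, 0.70 and 0.25 with an estimated correlation). Short genes as a whole were higher in puberty, and with offsets for gene length the ribosomal median was 0.27, with 3 genes higher in place of 17. TPH1, DDC and ASMT, which encode enzymes of melatonin synthesis, were not called. In all, 971 genes rose and 935 fell in puberty. Most changes were small, with 91.1% of the 1906 called genes under 2-fold and a median absolute log2 fold change of 0.53. Only 85 of the risers and 84 of the fallers reached 2-fold. All called genes had groups that did not overlap, as did 34.8% of all tested genes, where chance gives 10%.

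These calls rested on each library to a large degree. Without prepuberty replicate 1, edgeR called 0 genes in either direction, with 3901 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.061. On the same 5 libraries limma-voom also called 0 genes, while DESeq2 called 933 higher and 842 lower. Higher and lower calls numbered 532 and 518 without prepuberty replicate 2, and 281 and 305 without prepuberty replicate 3. They numbered 368 and 439 without puberty replicate 1, 269 and 269 without puberty replicate 2, and 729 and 550 without puberty replicate 3. All 1906 genes kept their direction in each of these fits, which share 5 libraries with the full one.

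Shorter genes were higher and longer genes lower in puberty. Spearman's rho of log2 fold change and listed gene length was -0.28 across the tested genes. The median length was 891 nt for genes that rose, 3802 nt for genes that fell and 1903 nt for all tested genes. Of 893 genes of 300 to 500 nt, 179 rose and 7 fell, and of 837 genes over 7000 nt, 8 rose and 183 fell. With offsets that removed this trend, 441 genes were higher and 444 lower, 826 of them called in both fits, and 1903 of the 1906 called genes kept their direction. The largest unadjusted p of a called gene was 0.0057 without the offsets and 0.0027 with them, so a gene whose fold hardly moved could lose its call. With these offsets and without 1 library, edgeR called 0 genes when prepuberty replicate 1, prepuberty replicate 3 or puberty replicate 1 was left out.

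**Figure D1:**
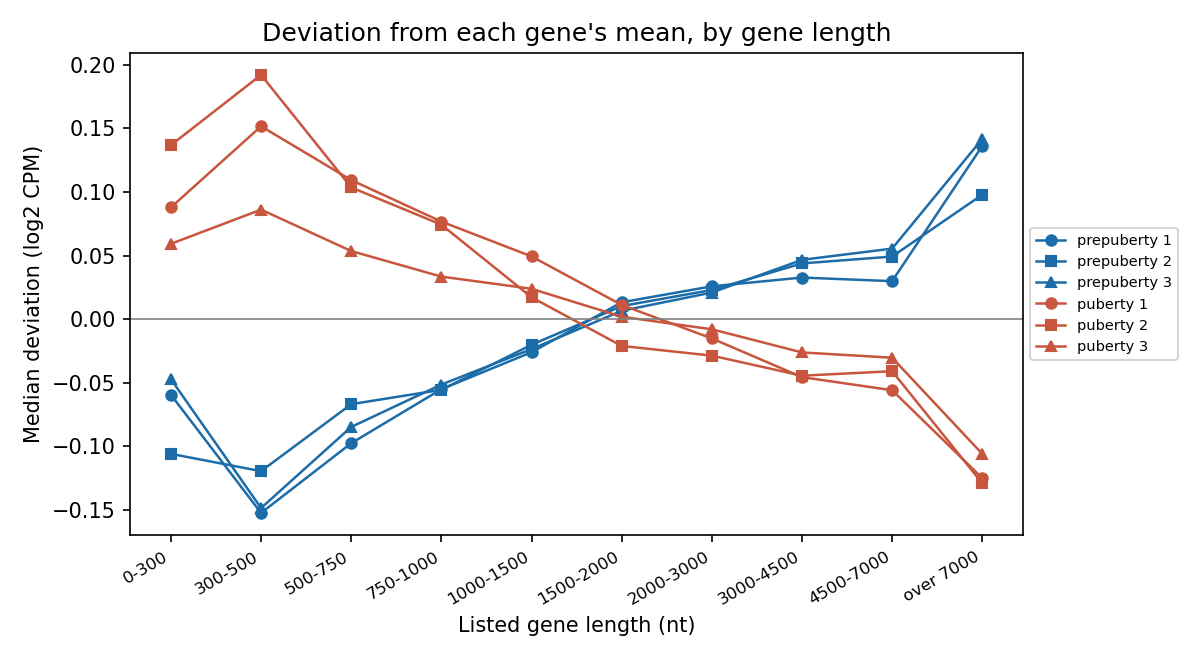
Median deviation of genes from their own mean log2 CPM over the 6 libraries (vertical axis) in 10 classes of listed gene length in nt (horizontal axis), with 1 line per library, prepuberty in blue and puberty in red. For genes of 300 to 500 nt the puberty libraries lie between 0.09 and 0.19 and the prepuberty libraries between -0.15 and -0.12, and for genes over 7000 nt the order is reversed.

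Among the 12 largest rises, GIP, which encodes the incretin hormone GIP, rose 6.77-fold (log2 fold change 2.76, SE 0.70, adjusted p = 0.046) from low counts, with 6, 35 and 5 counts in prepuberty and 161, 66 and 86 in puberty. DAO on chromosome 17 (6991388 to 7004168) rose 4.51-fold, from 2.19 ± 1.6 CPM to 9.91 ± 1.1 CPM (SD, n = 3 per group; log2 fold change 2.17, SE 0.43, adjusted p = 0.021). The dynein intermediate chain gene DYNC1I1 rose 3.67-fold to 42.7 ± 9.9 CPM (adjusted p = 0.020) and SHOX2 3.31-fold to 32.5 ± 11 CPM (adjusted p = 0.041). Other rises were RPRML (4.24-fold), the neurotrophic factor receptor GFRA3 (3.18-fold), ARHGEF16 (3.16-fold), SEC14L3 (3.08-fold), the tight junction gene CLDN1 (2.97-fold), SNAI3 (2.91-fold) and ADIRF (2.76-fold). GIP, RPRML, SHOX2, GFRA3, ARHGEF16 and ADIRF were no longer called with length-dependent offsets, with adjusted p-values of 0.072, 0.078, 0.055, 0.066, 0.061 and 0.080, although their log2 fold changes moved by less than 1 SE. The log2 fold change went from 2.76 to 2.62 for GIP (SE 0.70 in both fits), from 2.08 to 1.82 for RPRML (SE 0.52 in both) and from 1.73 to 1.8 for SHOX2 (SE 0.39 in both). It went from 1.67 to 1.61 for GFRA3 (SE 0.41 in both), from 1.66 to 1.73 for ARHGEF16 (SE 0.45 in both) and from 1.47 to 1.21 for ADIRF (SE 0.35 and 0.33). Without a count filter GIP, SHOX2, GFRA3 and ADIRF were not called either (adjusted p = 0.072, 0.091, 0.066 and 0.096). The folds of GIP, DAO and ARHGEF16 depended on prepuberty replicate 2, without which they were 18.1-fold, 7.70-fold and 5.07-fold.

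DCC, the netrin receptor, on chromosome 24 (52416425 to 53229521), fell 8.49-fold, from 27.5 ± 9.5 CPM to 3.25 ± 1.5 CPM (SD, n = 3 per group; log2 fold change -3.09, SE 0.37, adjusted p = 0.014). Of the 12 largest falls, CENPF, KIF11 and TOP2A are on the cell cycle list. The spindle gene ASPM fell 4.49-fold to 0.588 ± 0.17 CPM, the kinetochore gene CENPF 4.45-fold to 1.81 ± 0.55 CPM and the spindle motor KIF11 4.10-fold to 0.905 ± 0.39 CPM. TOP2A, a topoisomerase of dividing cells, fell 3.91-fold, from 16.9 ± 4.0 to 4.32 ± 1.4 CPM. NDC80 fell 3.14-fold and CDCA3 3.05-fold. The interleukin receptor gene IL20RA fell 4.5-fold, the axon guidance gene DRAXIN 4.24-fold, the microfibril gene FBN2 3.03-fold, SLITRK3 2.92-fold and the metalloproteinase gene ADAM12 2.88-fold. FBN2, SLITRK3 and ADAM12 were not called with length-dependent offsets, with adjusted p-values of 0.060, 0.066 and 0.060. Their log2 fold changes went from -1.60 to -1.40 (SE 0.37 and 0.36), from -1.55 to -1.49 (SE 0.39 in both fits) and from -1.52 to -1.45 (SE 0.38 in both).

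**Figure D2:**
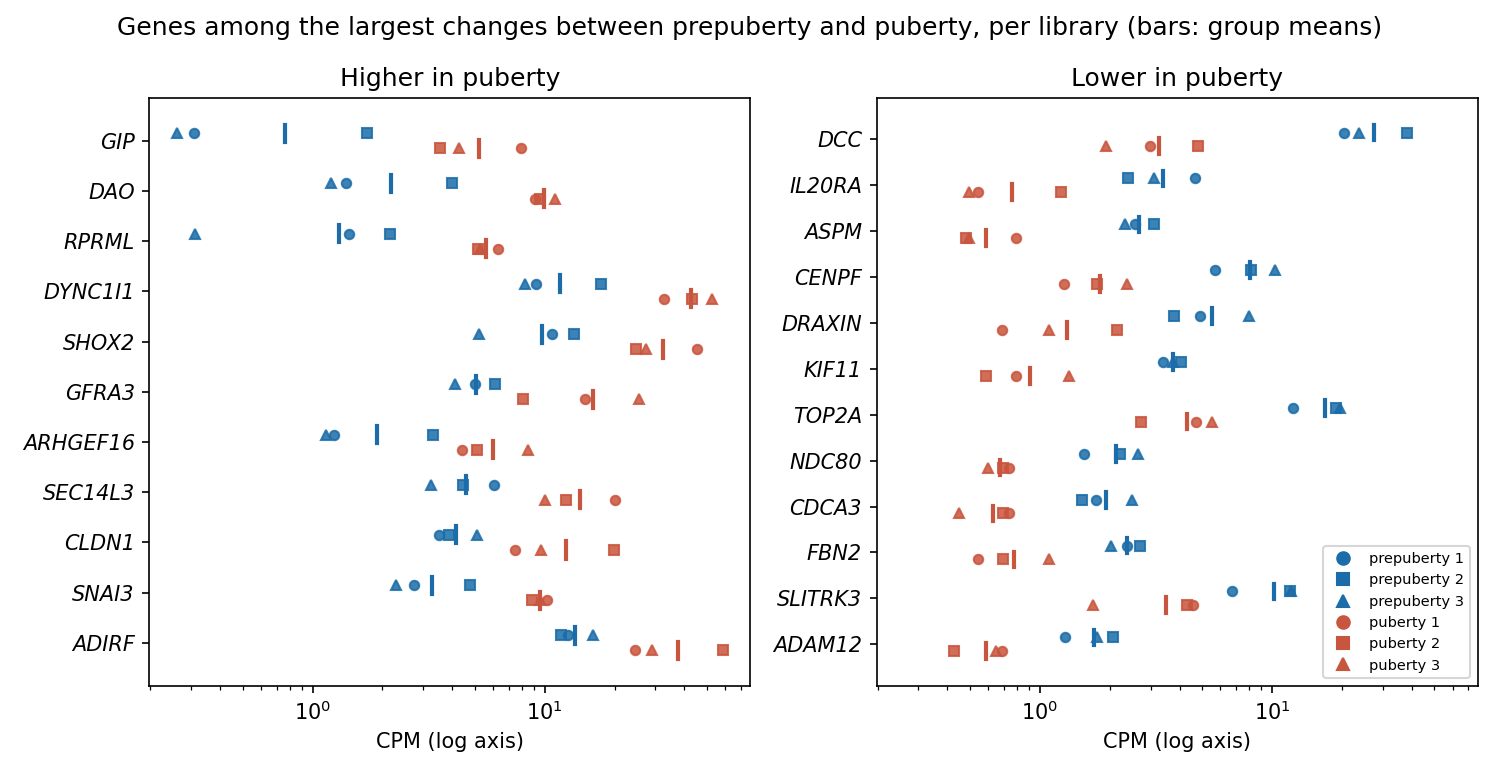
CPM on a log axis (horizontal) for genes among the 12 largest rises and for the 12 largest falls (vertical), with 1 point per library, prepuberty in blue and puberty in red, and a bar at each group mean. The groups do not overlap for any of these genes, and DCC goes from a mean of 27.5 CPM in prepuberty to 3.25 CPM in puberty.

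The melatonin pathway did not pass. TPH1, which encodes the first enzyme of the pathway, on chromosome 15, was at 2300.5 ± 287 CPM in prepuberty and 2538 ± 575 CPM in puberty (log2 fold change 0.14, 95% interval -0.23 to 0.52, adjusted p = 0.61). ASMT, which encodes the last enzyme, had a log2 fold change of 0.09 (-0.45 to 0.63, adjusted p = 0.83), and DDC, which encodes the second, of 0.03 (-0.35 to 0.40, adjusted p = 0.94). The sign of these 3 differences turned when single libraries were left out. Of the 10 measured genes of the list, QDPR and SPR, which act in the supply of the cofactor tetrahydrobiopterin, rose 1.33-fold and 1.27-fold. Adjusted over the list alone, 2 genes rose and 1 fell, and the list had an adjusted camera p of 0.56. The list of pinealocyte identity and phototransduction had an adjusted p of 0.82, with 36 genes measured. In it the transcription factor gene ISL2 rose 1.42-fold and UNC119 1.29-fold, and RBP3 fell 1.56-fold. Of 23 clock genes, CLOCK fell 1.54-fold, RORB 1.51-fold and RORA 1.38-fold (list adjusted p = 0.56). QDPR, SPR, UNC119, RBP3 and RORA were not called with length-dependent offsets, with adjusted p-values of 0.157, 0.060, 0.155, 0.082 and 0.29. The log2 fold change moved by less than 1 SE for SPR (0.35 to 0.36, SE 0.10 and 0.09) and RBP3 (-0.64 to -0.55, SE 0.16 in both fits). It moved by more for QDPR (0.41 to 0.28, SE 0.11 in both), UNC119 (0.37 to 0.23, SE 0.09 in both) and RORA (-0.46 to -0.20, SE 0.11 in both).

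Of the 35 lists tested, 6 were higher and 2 lower in puberty with camera at the preset correlation, and 0 passed with an estimated correlation. A lost call in the second test does not by itself show correlated genes. Antioxidant defence had an estimated correlation of -0.013, below the preset 0.01, yet its unadjusted camera p went from 0.00026 to 0.016. Nuclear-encoded genes of oxidative phosphorylation had a median log2 fold change of 0.41 and an adjusted p of 2.6e-09, or an adjusted p of 0.25 with an estimated correlation. Of 21 measured, 15 rose and 0 fell, with the same counts adjusted over the list alone. NDUFA2, a subunit of complex I, rose 1.82-fold, from 63.7 ± 2.4 to 116 ± 12 CPM (adjusted p = 0.013), UQCRQ 1.64-fold, NDUFA6 1.62-fold and NDUFS6 1.61-fold. The listed lengths of these genes were short, with a median of 978 nt. With length-dependent offsets the median was 0.37 and 11 genes were higher. The 12 measured mitochondrially encoded genes had a median of 0.50 (adjusted p = 0.00014, or 0.70 with an estimated correlation). Of them 3 rose, COX1 (2.32-fold), COX2 (1.77-fold) and ND3 (1.79-fold), or 8 adjusted over the list alone. COX3 had a log2 fold change of 0.47 (adjusted p = 0.060). With length-dependent offsets the median was 0.39 and 2 genes were higher. The list, chosen as a sign of RNA quality, had median deviations of 0.0013 in puberty replicate 1, 0.50 in puberty replicate 2 and 0.22 in puberty replicate 3, and of -0.40, -0.25 and -0.21 in the prepuberty libraries. Copies of mitochondrial genes in the nuclear genome make these values uncertain.

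Cytosolic ribosomal protein genes had a median log2 fold change of 0.44 and an adjusted p of 9.9e-11, or an adjusted p of 0.70 with an estimated correlation. Only 25 of the 74 listed genes were measured. Of these 25, 17 rose, or 22 adjusted over the list alone, and 0 fell. RPS28 rose 2.0-fold, RPS21 1.58-fold, RPLP2 1.53-fold and RPL11 1.47-fold. Their median listed length was 483 nt, in the classes of length that were higher in puberty. With length-dependent offsets the list median was 0.27 and 3 genes were higher. Ribosomal protein genes have many near-identical pseudogenes, and RPS28 overlaps a gene on the other strand, so their counts are uncertain.

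The cell cycle list was lower, with a median log2 fold change of -0.41 and an adjusted p of 0.00014, or an adjusted p of 0.25 with an estimated correlation. Of 25 measured genes 5 fell, or 11 adjusted over the list alone, and 0 rose. Besides CENPF, KIF11 and TOP2A, the microtubule-binding gene NUSAP1 fell 2.50-fold, from 6.59 ± 1.3 to 2.63 ± 0.58 CPM. With length-dependent offsets the median was -0.44 and 5 genes were lower.

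Antioxidant genes had a median of 0.33 and an adjusted p of 0.0019, or an adjusted p of 0.25 with an estimated correlation. Of 20 measured, 5 rose, or 10 adjusted over the list alone, among them the heme oxygenase gene HMOX1 (1.67-fold), the peroxiredoxin gene PRDX5 (1.53-fold), the secreted glutathione peroxidase gene GPX3 (1.5-fold) and NQO1 (1.33-fold). With length-dependent offsets GPX3 and NQO1 were not called (adjusted p = 0.057 and 0.136), with log2 fold changes of 0.43 (0.58 without the offsets, SE 0.11 in both fits) and 0.28 (0.41 without, SE 0.10 and 0.11). Chaperones and the unfolded protein response had a median of 0.16 and an adjusted p of 0.029, or an adjusted p of 0.78 with an estimated correlation. Of 22 genes 3 rose, SDF2L1 (1.99-fold), HSPB1 (1.77-fold) and HSPB8 (1.41-fold), also adjusted over the list alone, and BAG3 had a log2 fold change of 0.41 (adjusted p = 0.086). That list did not pass without prepuberty replicate 1, prepuberty replicate 3 or puberty replicate 1 (adjusted p = 0.068, 0.091 and 0.064), or with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.061). Its median was 0.09 without prepuberty replicate 3 and 0.10 with length-dependent or length-bin offsets. Insulin, IGF and PI3K signalling was lower, with a median of -0.20, a mean of -0.04 and an adjusted p of 0.041, or an adjusted p of 0.78 with an estimated correlation. Of 26 genes 6 fell, or 8 adjusted over the list alone, among them PIK3R1 (1.57-fold), PIK3CA (1.49-fold) and FOXO3 (1.36-fold). IGFBP6, which encodes an IGF-binding protein, rose 2.17-fold, and 2 genes rose adjusted over the list alone. The list lost its call with length-dependent offsets (adjusted p = 0.15). It also lost the call without prepuberty replicates 1 or 2 or puberty replicates 2 or 3, with adjusted p-values of 0.064, 0.11, 0.094 and 0.052. With a block for the replicate number the list did not pass either (adjusted p = 0.076). Its median was -0.11 with length-dependent offsets, -0.07 with length-bin offsets and -0.13 without puberty replicate 2.

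**Figure D3:**
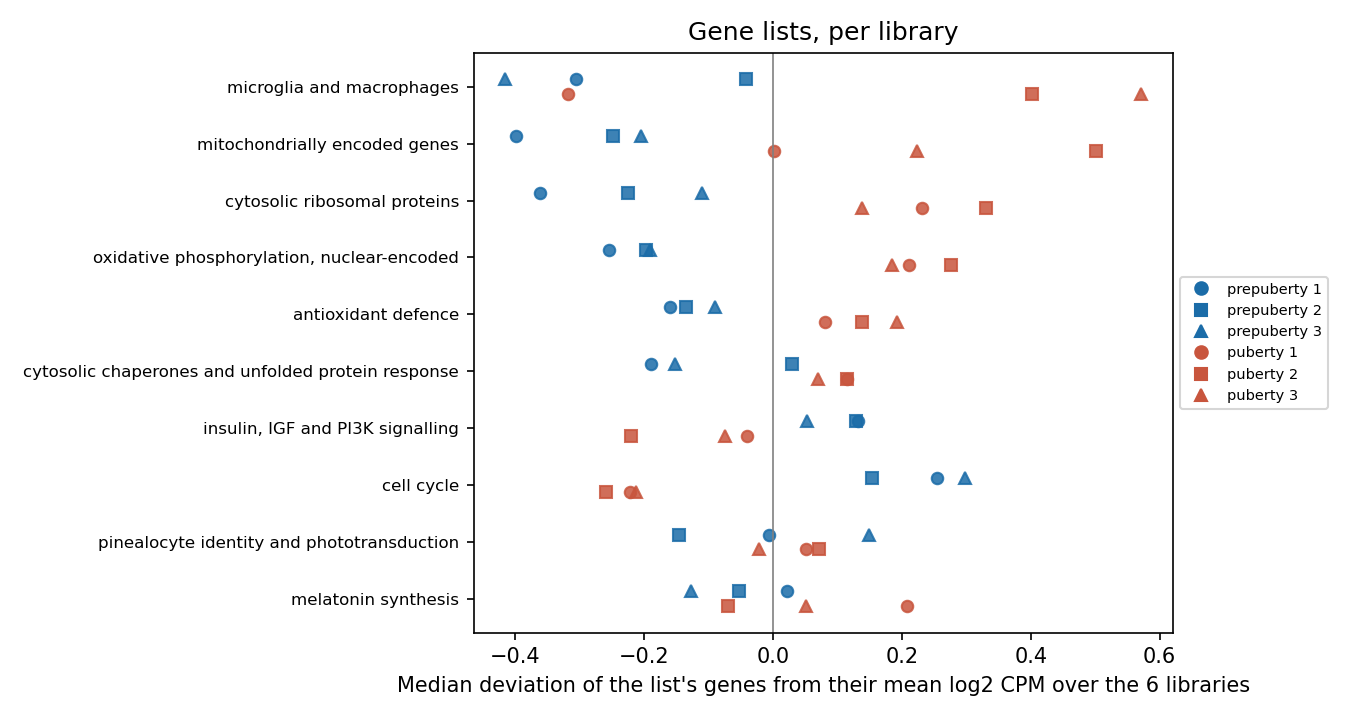
Median deviation of each list's genes from their mean log2 CPM over the 6 libraries (horizontal axis) for the 8 lists that passed camera at the preset correlation and for the melatonin and pinealocyte lists (vertical axis), with 1 point per library, prepuberty in blue and puberty in red. The groups lie apart for oxidative phosphorylation, ribosomal proteins and the cell cycle, whereas for microglia puberty replicate 1, at -0.32, lies among the prepuberty libraries.

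Markers of other cell types were compared in the same way, and a bare value in parentheses after a list is its adjusted camera p. The microglia and macrophage list had a median of 0.52 and an adjusted p of 0.0034, or an adjusted p of 0.81 with an estimated correlation. Of its 28 genes TYROBP rose 2.22-fold, and 0 rose adjusted over the list alone. C1QC, C1QB and TREM2 had log2 fold changes of 0.74, 0.68 and 0.87 (adjusted p = 0.057, 0.061 and 0.107). Without puberty replicate 3 this list had a median of 0.33 and did not pass (adjusted p = 0.13). In the list of 7 antigen presentation genes (adjusted p = 0.15), FCER1A, a receptor chain of mast and dendritic cells, had 1, 3 and 0 counts in prepuberty and 15, 22 and 11 in puberty. Astrocyte genes had a median of 0.29 (adjusted p = 0.085, or 0.032 with length-dependent offsets and 0.86 with these and an estimated correlation), and 4 of 18 rose, or 7 adjusted over the list alone, among them ALDH1L1 (1.53-fold), ID4 (1.45-fold) and ALDOC (1.29-fold). Of 22 oligodendrocyte genes CSPG4, also a pericyte marker, rose 1.43-fold (list adjusted p = 0.56). Of 14 Schwann cell genes SCN7A fell 2.31-fold (0.17), of 30 neuron genes SNCB rose 1.48-fold and MAP2 fell 1.45-fold (0.82), and of 12 habenula genes KCNIP1 fell 1.37-fold (0.41). Among 29 fibroblast and meninges genes CRABP2 rose 1.70-fold and SLC47A1 fell 2.83-fold (0.86). CRABP2 was not called without a count filter (adjusted p = 0.061), and the median of 0.07, the mean of -0.04 and the downward direction of the fibroblast list differ in sign. Adjusted p-values were 0.23 for lymphocytes, 0.94 for endothelium, 0.67 for pericytes, 0.56 for skeletal muscle and 0.17 for choroid plexus and ependyma, which passed without prepuberty replicate 3 or puberty replicate 1 (adjusted p = 0.041 and 0.035). The choroid plexus list had a median deviation of 0.78 in puberty replicate 2, against -0.05 and -0.16 in the other puberty libraries. Without puberty replicate 2 its median log2 fold change was 0.22 (adjusted p = 0.45). Erythrocyte and neutrophil lists, with 2 measured genes each, were not tested, and of these genes MMP9 rose.

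TTR, the main secretory transcript of the choroid plexus, was at 10089 CPM in puberty replicate 2, or 0.993% of its counts. The other puberty libraries had 464 and 206 CPM and the prepuberty libraries 88.5, 75.3 and 317 CPM.

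Other lists did not pass camera without offsets and held single called genes. Of 20 genes of the DNA methylation machinery (adjusted p = 0.073), the demethylation enzyme genes TET1, TET3 and TET2 fell 2.12-fold, 1.79-fold and 1.45-fold and AHCY rose 1.51-fold. With length-dependent offsets TET2 was not called (adjusted p = 0.078), with a log2 fold change of -0.28 (-0.54 without them, SE 0.09 and 0.08). Of 31 matrix genes (0.069), 6 fell and 1 rose. THBS1 fell 1.85-fold, ADAMTS1 1.99-fold and TNC 1.47-fold, and the gelatinase gene MMP9 rose 2.58-fold. Of 17 genes of reproductive hormones and receptors PDYN, which encodes prodynorphin, rose 2.42-fold, from 2.86 ± 0.52 to 6.91 ± 2.4 CPM (list adjusted p = 0.56). Of 19 hypoxia and glycolysis genes (0.069, or 0.036 with length-dependent offsets and 0.86 with these and an estimated correlation), ALDOC, TPI1 (1.30-fold) and BNIP3 (1.27-fold) rose. TPI1 overlaps another gene on its own strand and is uncertain. JUN rose 1.28-fold among 23 immediate-early genes (0.15) and MVD 1.40-fold among 21 genes of cholesterol synthesis (0.70). NPY1R fell 1.88-fold among 24 genes of neuropeptides and secretory granules (0.69), whose median of -0.03 and upward direction differ in sign. No gene was called in the lists of adrenergic and cAMP signalling (0.41), thyroid hormone and photoperiod response (0.82), interferon response (0.36), inflammatory cytokines (0.41), or GABA, glutamate and dopamine receptors (0.073). Of the genes named in the lists, ND3, RPLP2, HSPB1, TYROBP, SNCB, CRABP2, TNC, JUN, BNIP3 and TPI1 were also not called with length-dependent offsets, with adjusted p-values from 0.077 to 0.27. The log2 fold change moved by less than 1 SE for CRABP2 (0.77 to 0.71, SE 0.20 in both fits), HSPB1 (0.83 to 0.65, SE 0.20 and 0.19), TYROBP (1.15 to 0.88, SE 0.29 in both) and JUN (0.35 to 0.26, SE 0.10 and 0.09). It moved by more for ND3 (0.84 to 0.57, SE 0.19 in both), RPLP2 (0.61 to 0.34, SE 0.11 and 0.10), SNCB (0.57 to 0.32, SE 0.10 in both), TNC (-0.56 to -0.33, SE 0.11 in both), BNIP3 (0.35 to 0.16, SE 0.09 in both) and TPI1 (0.38 to 0.26, SE 0.10 in both).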

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

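The length-dependent and length-bin offsets and the thinning were chosen after seeing the data. Calls of 971 higher and 935 lower genes stayed within 1.5 times with RLE scaling (979 and 946), no count filter (1002 and 950), a filter of at least 1 CPM in 3 libraries (1071 and 937), DESeq2 (1425 and 1360), limma-voom (876 and 862), limma on log2(FPKM + 1) (844 and 634) or on log2(FPKM + 0.1) (857 and 653), and thinning (959 and 921). They moved to 1628 and 1617 at an adjusted p under 0.1 and to 85 and 84 with an absolute log2 fold change of at least 1, by construction. They were 441 and 444 with length-dependent offsets and 455 and 467 with length-bin offsets, and the cause of the drop was not tested. Leaving out 1 library gave 0 to 729 higher and 0 to 550 lower calls, with fewer samples in each fit. Of 35 lists 8 passed, 0 with an estimated correlation, 5 with fry (oxidative phosphorylation, ribosomal proteins, cell cycle, antioxidant defence and DNA methylation machinery), 7 with the filter of at least 1 CPM (chaperones lost their call), 9 with length-dependent offsets (astrocytes and hypoxia and glycolysis gained a call and insulin, IGF and PI3K signalling lost it), and 7 to 11 without 1 library. Uncalled values that changed sign without 1 library were those of DDC (log2 fold change -0.13 to 0.18), TPH1 (-0.060 to 0.26), ASMT (-0.048 to 0.32) and the list medians of melatonin synthesis (-0.0071 to 0.21) and pinealocyte identity (-0.053 to 0.11), and the cause was not tested. Of the 83 named genes that were called, 83 kept their direction and 56 their call with length-dependent offsets, and 78 kept their call without a count filter (GIP, SHOX2, GFRA3, ADIRF and CRABP2 lost it). Calls were kept by 76 with limma-voom, 62 with limma on log2(FPKM + 1), 0 without prepuberty replicate 1 and 35 to 56 without each other library. With a replicate block, edgeR called 366 higher and 354 lower genes, and 42 of the 83 kept their call. Camera at the preset correlation passed 7 lists with this block, and insulin, IGF and PI3K signalling lost its call (adjusted p = 0.076). Deviations of libraries with the same number correlated at 0.05, -0.10 and -0.10, so the numbers do not pair the libraries. Low counts kept 11656 of 28244 genes out of the tests, which leaves open whether they changed.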

Other observations

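All tests new to this part were chosen after the data were seen, except the count of list calls over other splits. Protein domain families, from the domain column of the deposited tables, were tested with camera in 196 families of at least 10 genes, and 17 passed at the preset correlation. With length-dependent offsets 10 passed, and 0 with an estimated correlation as well (adjusted p = 0.94). The 177 genes with a KRAB domain, found in zinc-finger repressors, had a median log2 fold change of -0.24 (-0.19 with the offsets). Of them 5.08% fell, no more than the 5.64% of all tested genes that fell, and 0 rose. Of 33 genes with an SNF2 helicase domain 10 fell, of 24 with a bromodomain 7 fell, of 17 with a JmjC domain 4 fell and of 28 with a HECT ubiquitin ligase domain 8 fell, with 0 rising in each. These are long genes, with median lengths of 5343, 3946, 4776 and 3318 nt, and with the offsets their medians went from -0.33 to -0.14, -0.30 to -0.22, -0.28 to -0.19 and -0.26 to -0.18. Of 30 SET domain genes 5 fell and 1 rose and of 20 PHD genes 4 fell, and of 43 histone genes 5 rose and 0 fell, but these families did not pass (adjusted p = 0.067, 0.29 and 0.15).

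Families that were higher included proteasome subunits, with 8 of 20 rising and a median of 0.33 (0.23 with the offsets), and LSM proteins of RNA processing, with 7 of 11 rising and a median of 0.50 (0.24 with the offsets). Of 14 Wnt ligand genes 2 rose, with a median of 0.62.

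Other splits of the 6 libraries into 3 against 3 number 10 with the real one, so no share under 0.05 can be reached. The real split called 971 and 935 genes, and the highest of the others was 1 gene in either direction, so 1 split reached each real count. For lists the real split passed 8, and 6 of the 10 splits passed as many, with 18 the highest of the others, which points to lists whose genes move together in single libraries. For oxidative phosphorylation, ribosomal proteins, cell cycle, antioxidant defence and DNA methylation machinery, 0 of the other 9 splits gave as low a p. By chance the real split gives the lowest p of a list in 1 of 10 lists. These lists were picked from 35, so a few such lists arise by chance and no conclusion is drawn from them.

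Short genes were higher and long genes lower in puberty. Unequal depth and listed genes alone were argued against, since Spearman's rho was -0.275 after thinning to equal totals and -0.274 among 11293 named genes outside the lists. RNA integrity or library preparation that differed between the groups may account for the trend and cannot be told apart from pubertal stage, because each library's own correlation with length separated the groups by 0.335. A trend with listed length as the whole cause of 2 higher lists was argued against. With the offsets both still passed at the preset correlation, with no overlap of the libraries' medians. Many listed lengths lack untranslated regions, so the offsets cannot remove a trend with full transcript length. The ribosomal pass is weak, since the estimated correlation of that list was 0.586, against the preset 0.01. The median of oxidative phosphorylation went from 0.41 to 0.367 and its risers from 15 to 11, and that of ribosomal proteins from 0.44 to 0.269 and its risers from 17 to 3, and neither passed with an estimated correlation as well (adjusted p = 0.27 and 0.86).

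The cell cycle list was lower in puberty. A trend with listed length as the whole cause was argued against by a median of -0.440 with length-dependent offsets, at the preset correlation. With an estimated correlation the list did not pass (adjusted p = 0.25, and 0.27 with the offsets). Fewer cells of 1 resident type dividing at the same rate may underlie the fall and stays open. The lowest median of the 14 cell type lists tested was -0.400, for Schwann cells, close to -0.41 for the whole cell cycle list. That median includes 7 of 25 cell cycle genes with a positive log2 fold change. The means of the 2 lists lay farther apart, at -0.63 for the cell cycle and -0.32 for Schwann cells. With length-dependent offsets the Schwann median was -0.309, farther from the cell cycle median of -0.440. The Schwann list itself did not pass camera at the preset correlation (adjusted p = 0.17). A lower rate of division with pubertal stage also stays open, as untested.

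TTR was 21.7 times higher in puberty replicate 2 than in the next library. Pubertal stage as the source of that value was argued against, since the lower of the other puberty libraries lay 111 CPM under the highest prepuberty library (difference -111 CPM). Whether TTR rose less steeply with stage is not decided by this, as puberty replicate 1, at 464 CPM, lay above every prepuberty library. Choroid plexus tissue in that library may be the source and stays open, since 5 of 7 other choroid plexus markers were highest there, short of the 3 in 4 set for that test. The shortfall rests on counting OTX2, also a pinealocyte gene, without which 5 of 6 would pass, and that variant was tried only after the result was seen. KL was at 42.8 CPM against at most 3.49 elsewhere and KCNJ13 at 84.8 against at most 4.96, while SLC4A5 was lowest there and OTX2 was at 450 to 573 CPM in all libraries.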
